A study of Caenorhabditis elegans with 14 samples.

How the data were processed

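RNA-seq libraries were made from rRNA-depleted total RNA of wild-type (strain YY2224) and akap-17(-) (strain YY2287) worms grown at 20 °C, per the labels' protocols. For RIP-seq, untagged (YY2224) and 3xFLAG::AKAP-17 (YY2393) worms were fixed in formaldehyde (1.8%), then sonicated, and RNA bound to anti-FLAG M2 beads was sequenced, per the labels' protocols. RNA-seq reads were processed with FastQC 0.12.1, Trim Galore 0.6.7 and STAR 2.7.9a, and RIP-seq reads with FastQC 0.11.8, Trim Galore 0.6.2, STAR 2.7.9a and Picard, on genome build WBcel235, per the submitters' processing notes. What Picard did is not given in the sources used here.

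The authors deposited RIP-seq data as whole-number read counts per window of at most 100 bp, with 712244 windows tiling the bodies of 46904 genes, introns included, and a reporter contig of 45 windows. Reads were counted without strand, since all 983 identical windows of genes on opposite strands held equal counts. Windows overlapped by another gene (10.6%) were left out, which left 17394 genes without a window, and the remaining windows were summed per gene. Symbols came from a gene name table for 44017 genes, and biotypes from RefSeq for 46706, of which 173 were matched by overlap, akap-17A among them. The planned restriction to exonic windows and the planned test of inverted-repeat loci needed a genome and annotation and were not run, so gene-body windows were used.

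Neighbouring windows often held exactly equal counts in all 8 libraries. Among pairs with at least 100 reads, this was so for 26.7% of 30203 pairs inside introns named in the event tables, 0.1% of 7010 pairs inside exons, and 13.5% of 238258 pairs overall. Reads spliced across an intron thus appear to be counted in each window they bridge, and summed gene counts can hold such reads several times. To guard against this, genes were tested again with equal neighbours counted once and with the fullest window alone. These alternatives, the test of windows, the thinning of IP libraries, the crossing of input numbers and the choice of the reporter were made after seeing the data. The comparison of introns with exons was also added after seeing the data, and it and the thinning were set before their own results were seen. The tests of strain, skipping reads, chance overlap, depth and near-equal windows were chosen after the results were seen. So was the correlation of window ratios along the reporter. The comparisons of the report, their tests and thresholds and the other alternatives were fixed before the data were examined, except 2 edits to the 21 gene lists: the alias akap-17A was added, and all protein-coding genes of the mitochondrial genome were added to the mitochondrial list.

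The authors deposited the RNA-seq data as event tables in the layout of rMATS, with a p-value, an FDR, inclusion levels and junction counts per event, per the file headers. The version and settings of rMATS are not given in the sources used here, and no test of these events was rerun. Per-library values of these tables were used to describe events only, and sets were not assigned a genotype.

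Genes were tested with edgeR 4.0.16 (quasi-likelihood, trimmed-mean factors, filterByExpr) in R 4.3.3 over all 8 libraries, which share one estimate of the spread, with Benjamini-Hochberg adjustment at 0.05. Contrasts were tagged against untagged IP, the same difference less that in input, and tagged against untagged input. CPM use the scaled library size. Lists were tested with camera of limma 3.58.1 and adjusted over 21 lists. Windows were kept with at least 10 reads, scaled, in both libraries of an IP group, and equal neighbours were counted once, which left 164892 windows. On simulated counts, changes were planted only in genes with a mean IP log2 CPM of at least 3, so recovery below that was not measured. The gene test recovered 36% of 2-fold and 95% of 4-fold changes in the IP (7 unchanged genes called, with 16441 genes tested). In the input-adjusted contrast it recovered 13% and 81% (8 unchanged genes called). The window test recovered 94% of 4-fold changes (5 unchanged windows called, with 20000 windows tested). Simulated windows were drawn independently, whereas real neighbours can share reads, so these window figures do not carry over to the real calls.

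Named genes followed a fixed rule: per comparison the 10 with the highest and lowest fold change past the threshold with separated libraries and log2 CPM of at least 3, all members of the AKAP-17 and RNA ligation list, and up to 3 members per direction of each list by p. For splicing, the 5 events per type with the largest difference past the thresholds and non-overlapping levels were named, and passing events of 3 lists. The log2 CPM in the rule for genes is a mean over all 8 libraries, input included. Folds against groups without reads used a floor of 3 reads per library. Floors cover counting error only, and the bootstrap interval covers the spread among genes only. Alternatives were RLE scaling, library totals, DESeq2 1.42.0, no low-count filter, a replicate block, fewer libraries in the fit, each library left out, all windows of a gene, and no ribosomal or mitochondrial genes. Between replicates, the chi-square per degree of freedom was 15.3 to 86.1, with correlations of log2 CPM from 0.914 to 0.951. Reads counted in several windows raise this chi-square, so it cannot tell differences between replicates from sampling noise. Scripts ran in Python 3.11.15 with scipy 1.17.1.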

Results

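The data came from Caenorhabditis elegans and addressed AKAP-17, a protein of a splicing system that removes DNA transposons from messenger RNA. RNA immunoprecipitation with sequencing (RIP-seq) asked which RNAs were recovered with 3xFLAG-tagged AKAP-17. Tagged worms (3xFLAG::AKAP-17) and untagged worms each gave an input and an anti-FLAG immunoprecipitate (IP), with 2 libraries in each of 4 groups. Separately, 3 RNA-seq libraries of wild-type and 3 of akap-17(-) young adults were compared for splicing. Window counts summed to 221541292 and 202765460 in the untagged input, 179158650 and 233697029 in the tagged input, 13784632 and 13678133 in the untagged IP, and 19607634 and 18303857 in the tagged IP. Positions are on genome build WBcel235. Ribosomal RNA took 72.9 to 76.1% of the input counts, 18.4 and 17.6% of the untagged IP counts, and 13.4 and 15.3% of the tagged IP counts. Nothing in the labels says that libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

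The first comparison set the tagged IP against the untagged IP, which gives the background of the beads. Among called genes with a mean log2 CPM of at least 3 over all 8 libraries, input included, drh-2, wago-2 and prg-2 had the largest increases. None of them is on the fixed list of small RNA pathway genes. wago-2 (WBGene00018862, chromosome I, 5368478 to 5372643), named for Argonaute proteins, had 175 ± 4.16 CPM (read counts scaled to library size) in the tagged IP and 13.5 ± 0.0375 in the untagged IP (mean ± SD, n = 2), a log2 fold change of 3.70 ± 0.08 (SE). prg-2 (WBGene00004179, IV, 6526962 to 6529802), of the PIWI family, had 226 ± 12.8 against 18.2 ± 0.573 CPM (n = 2), a log2 fold change of 3.64 ± 0.10. Both are pseudogenes in the annotation, as is drh-2 (WBGene00001091, IV, 6613918 to 6618498), which stood at 98.4 ± 12.6 against 1.29 ± 0.108 CPM (n = 2), a log2 fold change of 6.25 ± 0.49. The mRNA of akap-17 itself (akap-17A in the annotation, WBGene00000854, III, 7518628 to 7520845) stood at 129 ± 10.5 against 26.7 ± 2.21 CPM (n = 2), a 4.84-fold difference (log2 2.28 ± 0.13).

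Of 17412 genes tested with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, the Tc1 reporter counted as a gene, 85 were higher (the reporter among them) and 4 lower in the tagged IP at an adjusted p below 0.05. The adjusted p was 2.44e-05 for wago-2, 5.57e-05 for prg-2, 0.00651 for drh-2 and 0.0018 for akap-17 (edgeR), and both tagged libraries lay above both untagged ones for each. Of the 85, 74 were protein coding and 9 were pseudogenes, out of 842 pseudogenes tested (odds ratio 2.34, two-sided Fisher's exact p = 0.0214). The count depended on each library: it was 4 without untagged IP replicate 1, 12 without untagged IP replicate 2, 20 without tagged IP replicate 1 and 13 without tagged IP replicate 2, with 0, 0, 34 and 17 genes lower. DESeq2 called 473 higher and 509 lower, and 65 of the 85 were called in no run with an IP library left out, whereas wago-2, prg-2, unc-22 and C05C9.3 were called in all 4. Of these, unc-22 was not called when its fullest window alone was tested (1.38 ± 0.24). The call of drh-2 ended without untagged IP replicate 1 (6.09), untagged IP replicate 2 (6.26) or tagged IP replicate 2 (6.05).

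At a mean log2 CPM of at least 3, the 10 called transcripts with the largest increases also held T05E12.3, C05C9.3, C16A11.5, trp-2, B0303.11, hsf-2 and kvs-5, at log2 fold changes of 3.48 ± 0.31, 3.28 ± 0.14, 3.26 ± 0.46, 3.22 ± 0.41, 3.10 ± 0.17, 3.08 ± 0.41 and 2.60 ± 0.25 (edgeR, adjusted p from 0.000418 for C05C9.3 to 0.0465 for C16A11.5). T05E12.3, C05C9.3 and hsf-2 reached that mean through their input counts. Their IP means were 3.03, 7.53 and 3.83 CPM in tagged and 0.27, 0.77 and 0.45 CPM in untagged worms. trp-2 encodes a TRP family channel. In their fullest window, T05E12.3 had 0 reads in both untagged IP libraries against 30 and 35, at least 7.22-fold higher against a floor of 3 reads per library, and C05C9.3 had 0 against 28 and 26, at least 5.96-fold higher. T05E12.3 lost its call without untagged IP replicate 1 (3.83), untagged IP replicate 2 (3.08) or tagged IP replicate 2 (3.34). B0303.11 lost it without untagged IP replicate 1 (2.97), and trp-2 without untagged IP replicate 1 (2.65) or either tagged IP library (3.03 and 3.25). C16A11.5, hsf-2 and kvs-5 lost theirs whichever IP library was left out, at 2.88 to 3.59, 2.52 to 3.74 and 2.39 to 2.68, and kvs-5 fell to 1.9 with equal windows counted once. hsf-2 rested on few reads, 0 and 4 against 32 and 11 in its fullest window. The 4 lower transcripts were srh-255, the collagen gene col-125 (log2 -1.14 ± 0.14), the mitochondrial ribosomal RNA KEF34_r02 (-0.71 ± 0.10) and C41D11.3 (-0.54 ± 0.08). srh-255 had 2 and 2 reads against 0 and 0 in its fullest window, under the floor, so no fold is given, and C41D11.3 turned to 0.51 when its fullest window alone was tested. Most of the col-125 difference was already in the input (-0.87 ± 0.14), and its input-adjusted value of -0.27 ± 0.20 did not pass. The calls of these 4 ended whichever IP library was left out, with col-125 at -1.36 to -1.08, KEF34_r02 at -0.89 to -0.67 and C41D11.3 at -0.66 to -0.57.

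**Figure D1:**
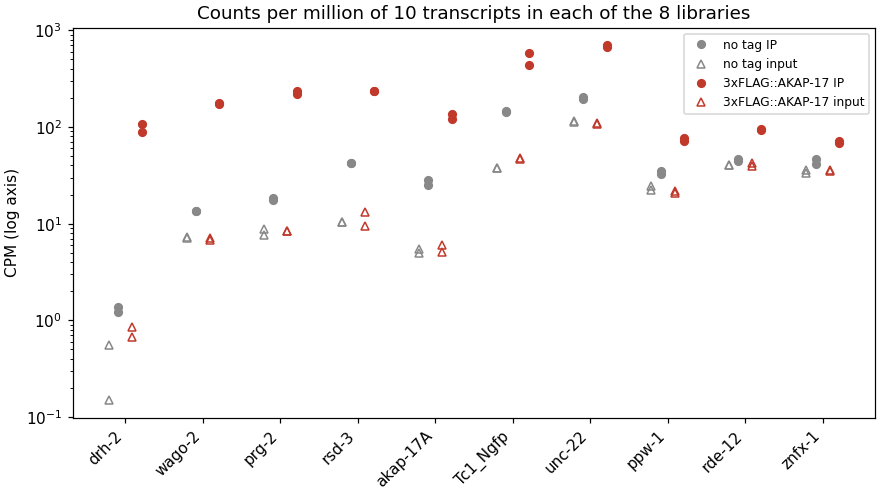
CPM (log axis) of 10 transcripts, with each point a library, filled circles for IP, open triangles for input, grey for untagged and red for tagged worms. The tagged IP points of wago-2, near 175 CPM, lie above its untagged IP points, near 13.5 CPM, while its 4 input points lie near 7 CPM.

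The Tc1 reporter, a contig of 45 windows whose name (Tc1_Ngfp) refers to the DNA transposon Tc1 and to GFP, was higher in the tagged IP. It had 443 and 582 CPM there against 146 and 143 CPM in the untagged IP, a log2 fold change of 1.82 ± 0.13 (edgeR, adjusted p = 0.00386, n = 2). Of its 35 tested windows, 26 were higher and 0 lower at an adjusted p below 0.05 in edgeR's test of windows. Of these, 11 had a log2 fold change of at least 2. A window at bases 2001 to 2100 (2.09 ± 0.28) stood apart from the others, which lay between bases 2801 and 4000. The highest reached 3.07 ± 0.31 at bases 3801 to 3900. The fullest window, bases 2901 to 3000, held 2779 and 2923 reads in the tagged IP and 514 and 480 in the untagged IP. Windows at bases 4101 to 4200 and 4201 to 4300 did not pass, at -0.30 ± 0.34 and 0.01 ± 0.45. The window ratios of the libraries numbered 1 and of those numbered 2 correlated along the contig (Pearson's r 0.72, Spearman's rho 0.74), across windows that are not independent replicates. The call of the whole reporter ended without untagged IP replicate 1 (1.76, adjusted p = 0.1, edgeR) and without untagged IP replicate 2 (1.73, adjusted p = 0.106, edgeR), where the range over 15 alternatives was 3.87e-34 to 0.106. For akap-17 it ended without untagged IP replicate 1 (2.12, adjusted p = 0.0652, edgeR), with a range of 6.69e-44 to 0.0652 over 15 alternatives.

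**Figure D2:**
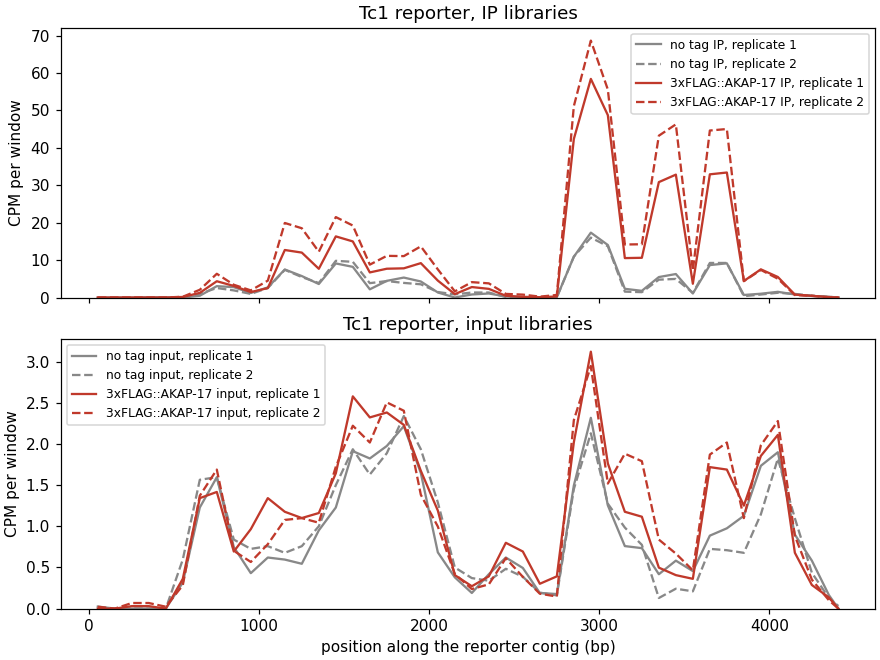
CPM in each window along the Tc1 reporter contig (position in bp), for the IP libraries above and the input libraries below, with grey for untagged and red for tagged worms and solid and dashed lines for replicates 1 and 2. In bases 2901 to 3000 the tagged IP libraries reach 58.4 and 68.7 CPM and the untagged ones 17.3 and 16.01 CPM.

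Gene lists were tested together with camera, which compares a list with all other genes, using a preset correlation of 0.01. Small RNA pathway genes were higher as a list (median log2 fold change 0.16, 31 of 41 positive, adjusted p = 0.00113, camera, and adjusted p = 0.143 with an estimated correlation), and 3 of the 41 passed alone: ppw-1, an Argonaute gene, at 1.12 ± 0.10, rde-12 at 1.06 ± 0.08 and znfx-1 at 0.68 ± 0.09. With an IP library left out, rde-12 was called in 1 of 4 runs and ppw-1 and znfx-1 in 0. Adjusted over the list alone, 8 passed. Neuronal genes had a median of 0.71 (0.59 with the member at 0 in a group set at its bound), with 0 of 20 passing, 17 positive, and ric-4 at 1.86 ± 0.53 and nlp-21 at 1.51 ± 0.38 not passing. The list was called higher (camera adjusted p = 0.00409, and 0.143 with an estimated correlation). The AKAP-17 and RNA ligation list, with 7 of 7 positive, had 1 member passing, akap-17 (median 0.24, camera adjusted p = 0.00664, and 0.143 with an estimated correlation). The others did not pass: arch-1 (0.56 ± 0.33), caap-1 (0.37 ± 0.19), rnp-7 (0.24 ± 0.28), rtcb-1, the RNA ligase (0.12 ± 0.33), ire-1 (0.07 ± 0.14) and its splicing target xbp-1 (0.07 ± 0.12). Pseudogenes were called higher as a list (median 0.46, 9 of 842 passing, 13 adjusted over the list alone, camera adjusted p = 0.00724, and 0.143 with an estimated correlation), but 238 of them had no read in a group, and with those at their bound the median was 0. Of the 16 lists called, 0 held with an estimated correlation. Correlation between members does not account for this in every list. The estimates were -0.0121 for small RNA pathway genes and -0.107 for the AKAP-17 and RNA ligation list, below the preset 0.01. With an estimated correlation, camera is limited to the few residual degrees of freedom of 8 libraries in 4 groups. The loss of a call under that setting therefore cannot decide against a list.

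Ribosomal protein genes were lower as a list, with 0 of 78 positive and a median of -0.33 (camera adjusted p = 2.28e-39, and adjusted p = 0.143 with an estimated correlation). None passed over all genes in edgeR, while 69 passed adjusted over the list alone. rpl-35, a large-subunit protein gene, stood at -0.44 ± 0.07. Histone genes had a median of -0.32 (camera adjusted p = 1.35e-08, and adjusted p = 0.229 with an estimated correlation), collagens -0.34 with 8 lower adjusted over the list alone (3.8e-06 and 0.143), mitochondrially encoded genes -0.47 (8.94e-05 and 0.368), and pharyngeal muscle genes -0.43 with 2 lower adjusted over the list alone (0.00497 and 0.231). Much of this was already in the input for pharyngeal muscle genes (input median -0.32, input-adjusted median 0.09, adjusted p = 0.842 upward, camera) and mitochondrially encoded genes (input median -0.25, input-adjusted median -0.22). Body-wall muscle genes had a median of -0.23, with 2 higher and 9 lower adjusted over the list alone (0.00409 and 0.276), in which unc-22, the gene of the giant muscle protein twitchin (WBGene00006759, IV, 11972697 to 12011007), went the other way at 1.79 ± 0.06. It had 688 ± 13.04 against 199 ± 5.45 CPM (n = 2). Germline and oocyte genes had a median of -0.12 (0.00051 and 0.254), splicing factors -0.08 (0.0359 and 0.16), snoRNAs -0.12 with a mean of 0.56 (0.0359 and 0.347) and SR protein genes -0.15 (0.0227 and 0.389). Library totals in place of trimmed means raised the median of all genes by 0.126, and that common shift took the medians of germline genes, splicing factors and snoRNAs to 0.01, 0.05 and 0.01 without moving them against other genes. Among splicing factors, uaf-1, a U2AF subunit gene, stood at 0.82 ± 0.16 and did not pass.

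Ribosomal RNA genes were called lower, 6 of them adjusted over the list alone (0.000887 and adjusted p = 0.404 with an estimated correlation) with a median of 0 and a mean of 0.74, and snRNA genes (0.0254 and 0.435) had a median of -0.17 and a mean of 0.40, so the mean ran against the test in both. The means are inflated by 11 of 21 rRNA and 7 of 31 snRNA genes with no read in a group, and with those at their bound the medians were 0 and -0.13. Vitellogenins (median -0.09, camera adjusted p = 0.0553), tRNAs (0, 0.0948), intestinal genes (-0.20, with 1 higher adjusted over the list alone, 0.206), heat shock and unfolded protein response genes (-0.12, with 5 higher and 2 lower adjusted over the list alone, 0.687) and major sperm proteins (-0.41, with a mean of 0.59, 0.984) did not pass. The shift that library totals gave all genes took the medians of vitellogenins and heat shock genes to 0.03 and 0.01. Within the heat shock list, 4 small heat shock genes passed, copies of hsp-16.1 and hsp-16.48 (V). Their fullest windows held practically the same reads in every library (110 or 111, 80, 82 and 66 in the inputs), so they are not 4 separate results, and the gene name table gives each symbol to 2 genes. A copy of hsp-16.1 was not called with equal windows counted once, nor any copy with the fullest window. They had 0 reads in the untagged IP and 8 to 10 in the tagged IP in their fullest windows, at least 2 to 2.21-fold higher, and were called in 0 of the 4 runs with an IP library left out.

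The second comparison asked whether the difference between tagged and untagged worms was larger in the IP than in the input. Of 17412 genes, 16 were higher and 0 lower (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05, with 1096 higher and 712 lower at an unadjusted p below 0.05, and 351 higher and 283 lower by DESeq2). Those with a mean log2 CPM of at least 3 included wago-2 (log2 3.74 ± 0.11), prg-2 (3.59 ± 0.14), B0303.11 (3.13 ± 0.22), ints-7 (2.56 ± 0.16), rsd-3 (2.34 ± 0.21), W04B5.3 (2.20 ± 0.18), akap-17 (akap-17A, 2.19 ± 0.18) and unc-22 (1.87 ± 0.09). T05E12.3 (3.93 ± 0.40) and C05C9.3 (2.88 ± 0.17) were also called. Their summed CPM were lower in the tagged IP than in the tagged input, at 3.03 ± 0.237 against 14.3 ± 0.499 and 7.53 ± 0.919 against 227 ± 11.7 (n = 2). These sums appear to hold the same input reads many times. C05C9.3 had 15593 and 19287 summed tagged input reads but 158 and 192 in its fullest window, against 28 and 26 in the tagged IP. T05E12.3 had 83 and 109 there against 30 and 35. The size of the gap is thus not read from the sums. ints-7 encodes a subunit of the Integrator complex, and part of its value came from the input, where it stood at -0.85 ± 0.11, against 1.71 ± 0.12 in the IP. rsd-3 is a gene of RNA interference. Of the 16, 15 were also higher in the IP comparison. The other gene was nhr-116, at 3.87 ± 0.40, whose input difference was -2.03 and whose fullest window held 4 and 4 against 6 and 2 IP reads. The Tc1 reporter (Tc1_Ngfp) did not pass, at 1.49 ± 0.18 (edgeR, adjusted p = 0.068), nor did drh-2, at 5.19 ± 0.66 (adjusted p = 0.081, edgeR). Only wago-2, prg-2 and unc-22 were called whichever of the 8 libraries was left out. The count moved by over 1.5 times without untagged input replicate 1 (5 genes), untagged input replicate 2 (62), tagged input replicate 2 (29), untagged IP replicate 1 (3), untagged IP replicate 2 (3), tagged IP replicate 1 (9) and tagged IP replicate 2 (7). Lower genes, 0 with all libraries, numbered 7 without tagged input replicate 1, 18 without tagged IP replicate 1 and 16 without tagged IP replicate 2. The call of akap-17 ended without untagged input replicate 1 (2.24), untagged IP replicate 1 (2.04), untagged IP replicate 2 (2.21) or tagged IP replicate 2 (2.05), and with the fullest window alone (1.195). The reporter Tc1_Ngfp passed without tagged IP replicate 1 (1.60) or 2 (1.22).

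The third comparison looked for differences between strains in the input alone. The akap-17 mRNA (akap-17A) stood at 5.54 ± 0.666 CPM in tagged and 5.23 ± 0.298 CPM in untagged input (n = 2), a log2 difference of 0.09 ± 0.13, and the reporter Tc1_Ngfp at 47.2 ± 0.159 and 37.4 ± 0.0999 CPM, a difference of 0.34 ± 0.12. Neither passed in edgeR (adjusted p = 1 and 0.564). Of 17412 genes, 0 were higher and 0 lower by edgeR, with 582 higher and 751 lower at an unadjusted p below 0.05, and DESeq2 called 120 higher and 386 lower. Without tagged input replicate 1, edgeR called 18 higher and 8 lower, without untagged input replicate 2 it called 2 and 38, and without tagged input replicate 2 it called 0 and 13.

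The fourth comparison concerned splicing between wild-type and akap-17(-) worms. The authors' deposited table names its libraries only as set 1 and set 2, and which genotype each set holds is not stated in the sources used here, so directions are given by set number. The akap-17 transcript was not analysed here in these RNA-seq libraries. In the authors' deposited table, retained introns showed the largest differences: the intron of Y119C1B.10 at I, 4556016 to 4556062 had inclusion levels of 0.719 to 0.794 in set 1 and 0.132 to 0.268 in set 2, a difference of 0.554 (FDR = 0.041). In the authors' deposited table, the Y17G9B.4 intron (IV, 4752390 to 4752441) differed by 0.371, the F14D7.6 intron (V, 14305795 to 14305848) by 0.295 and the Y54G2A.36 intron (IV, 2901098 to 2901143) by 0.288, each higher in set 1. In the authors' deposited table, uaf-1 (III, 1067953 to 1068035), whose product recognises the 3' splice site, retained its intron at 0.678 to 0.808 in set 1 and 0.556 to 0.574 in set 2 (difference 0.186, FDR = 0.048). In the authors' deposited table, ppw-1 went the other way, with use of the downstream 5' splice site that adds bases 4186682 to 4186712 of chromosome I at 0.458 to 0.498 in set 1 and 0.721 to 0.754 in set 2 (difference -0.26, FDR = 0.0151).

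By the thresholds of an FDR below 0.05, an absolute difference of at least 0.1 and 10 junction reads per library, 7 of 8375 events passed in the authors' deposited table. Of these, 6 were retained introns and 1 was the ppw-1 splice site, and the seventh gene was cpt-2 (IV, 11181705 to 11181756, difference 0.121), named after its values were seen because it fell outside the 5 largest. In the authors' deposited table, 0 skipped-exon, 0 alternative 3' splice site and 0 mutually exclusive exon events passed, although 763, 148 and 102 had an unadjusted p below 0.05. On FDR alone, the authors' deposited table held 54 events, of which 49 had higher inclusion in set 1, 4 in set 2 and 1 a difference of 0. Of these 54, 35 had no skipping read in set 1 and some in every library of set 2. By contrast, 0 of 26 mirror events were called in the authors' deposited table. The split between the sets is thus not read as a direction of splicing change.

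**Figure D3:**
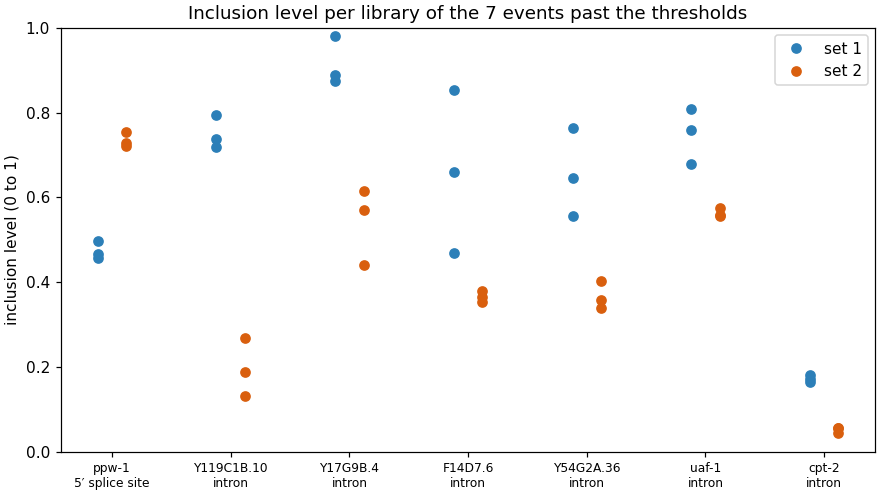
Inclusion level (0 to 1) of the 7 events past the thresholds in the authors' deposited table, with each point a library, blue for set 1 and orange for set 2. For ppw-1, set 1 lies at 0.458 to 0.498 and set 2 at 0.721 to 0.754.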

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

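The thinning of libraries and the comparison of introns with exons were added after the data were seen but before their own results, and the tests of strain, skipping reads, chance overlap and depth were chosen after the results were seen. In 16 genes the difference between tagged and untagged worms was larger in the IP than in the input by edgeR's test of that difference, wago-2 and prg-2 among them. Of 17394 genes left out of the comparisons because all their windows overlap another gene, 6535 could be tested when all windows were used, and 5 were called, all higher: nhr-114 (log2 1.10), math-26 (3.79), cls-3 (1.34), F56D5.4 (1.40) and C03A7.13 (3.61), by edgeR with adjusted p from 0.0187 to 0.0427. Their reads cannot be told from those of the overlapping gene.

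More genes were higher (85, the reporter included) than lower (4) in the tagged IP by edgeR, but not by DESeq2 (473 and 509) or without tagged IP replicate 1 (20 and 34) or 2 (13 and 17). For the 85 genes as a set, a strain difference present before the pulldown is argued against by the input. Their median log2 difference was 0.07 there (bootstrap 95% interval over genes 0.015 to 0.124) against a median of 1.52 in the IP. The interval holds no spread between libraries. This does not cover each gene: cpr-4 stood at 1.306 in the IP and 1.585 in the input, and asns-2 at 0.44 and 0.40. After thinning the IP libraries to the smallest total, 98.8% of the genes were called again. Thinning took every count of a gene sum as a separate read, though sums can hold a read several times. The totals matched also include ribosomal RNA, a larger share of the untagged IP. Thinning therefore cannot decide on deeper sequencing of the tagged IP. Whether intronic RNA was recovered more stays open: introns minus exons gave a median of -0.13 and -0.02 in the libraries numbered 1 and 2, but only 18.8% of the genes had both kinds of window, and spliced reads counted in introns make that comparison void. Recovery with AKAP-17 remains a hypothesis.

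Skipped-exon events past FDR 0.05 in the authors' deposited table numbered 30, of which 28 had higher inclusion in set 1. Of 30 events with no skipping read in set 1 and some in every library of set 2, 26 were called, against 0 of the 24 mirror events in the authors' deposited table (two-sided Fisher's exact p = 1.48e-11), with a median of 7 and 7.5 skipping reads per event. This is consistent with an unequal treatment of events with no skipping read in the software behind that table. A genotype effect on these exons was not tested.

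Genes with a changed splicing event were often higher in the tagged IP: 3 of 7 (ppw-1, Y119C1B.10 and cpt-2), where 0.0916 were expected among 3361 genes measured in both. Chance overlap gave a two-sided Fisher's exact p = 7.07e-05. Genes of matched depth in the pulldown gave a permutation p = 7e-05 over 100000 draws, which argues against pulldown depth as the source. The depth of junction reads in the RNA-seq libraries was not matched, so the draws cannot decide on that depth. The 3 genes stayed called with RLE factors, totals, DESeq2 and equal windows counted once, 2 of them with a replicate block, 2 with the fullest window, and 0 in any run with an IP library left out. That AKAP-17 acts on these transcripts is a hypothesis that was not tested. The tests address only the overlap, which was found in the same data.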

How the results depend on the processing

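The thinned libraries, equal windows counted once, the fullest window and the crossed numbers were chosen after seeing the data. The IP counts, 85 higher and 4 lower, became 48 and 7 with RLE factors, 158 and 2 with library totals, 473 and 509 with DESeq2, 149 and 11 with equal windows counted once, and 24 and 2 with the fullest window. Of the 85, 81 were called again with equal windows counted once and 21 with the fullest window. The lower count alone moved without the filter (10), with fewer libraries in the fit (14), all windows (1), no ribosomal or mitochondrial genes (8) and thinned libraries (2). Leaving out each IP library gave 4 to 20 higher and 0 to 34 lower, by construction with fewer samples and a lone library assumed to vary like the other groups. The 16 input-adjusted genes became 9 with totals, 351 higher and 283 lower with DESeq2, 41 and 2 without the filter, 25 and 1 with equal windows counted once, 6 with the fullest window, and 3 to 62 higher and 0 to 18 lower with a library left out. In the input, where 0 were called, totals gave 1 higher, DESeq2 120 higher and 386 lower, no filter 2 and 23, equal windows counted once 1 higher, the fullest window 2 higher, and left-out libraries 0 to 18 higher and 0 to 38 lower. Except where stated, the cause was not tested.

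The reporter stayed at 1.55 to 1.93 and akap-17 at 2.12 to 2.29 in the IP with a library left out. Input-adjusted, the reporter passed in DESeq2 (1.41), without the filter (1.48), with equal windows counted once (1.49) and with the fullest window (1.55), over 1.22 to 1.60 with a library left out. Input-adjusted akap-17 ranged from 2.04 to 2.31 with a library left out and no longer passed with the fullest window (1.195). The fold change of C41D11.3 reversed to 0.51 with the fullest window. The cause was not tested. Of 765 values of 24 single genes, 113 no longer passed, 12 newly passed and 1 that had passed, that of C41D11.3, reversed. The other 639 were counted as unchanged, which includes any change of sign in a gene that did not pass in the main test. Of 16 lists, 0 held with an estimated correlation, which leaves few degrees of freedom, and 8 in the input-adjusted contrast.

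With a replicate block, 26 genes were higher and 0 lower in the IP, 6 were input-adjusted, 0 differed in the input and 17 lists were called. Same-numbered libraries did not deviate together (correlations -0.24 to 0.01), so the numbers were not taken to pair libraries. Crossing the numbers of the tagged input left the input counts at 0. No test of the splicing events, paired or not, was run. The 7 events became 0 at an FDR below 0.01, 50 without a minimum difference and 11 without a minimum of reads in the authors' deposited table. The exonic windows and the inverted-repeat loci were not run. With 2 libraries per group, the gene test recovered 36% of simulated 2-fold changes in the IP among genes with a mean IP log2 CPM of at least 3, so smaller differences can be missed.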

Other observations

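The tests of windows in this part were chosen after the results were seen. In edgeR's test of 164892 windows, 1470 were higher and 778 lower in the tagged IP, and the higher windows fell in 238 genes. Windows are not independent, because bridging reads appear to be counted again. A near-equal neighbour, within 10% or 2 reads in every IP library, lay beside 76.3% of the lower windows, 29.6% of the higher and 36.9% of those not called. The longest run of lower windows held 444 windows of 12 genes at I 14984178 to 15040626, with medians of 399 and 408 reads in the untagged and 155 and 307 in the tagged IP. Numbers of windows are thus not numbers of separate loci. unc-22 held 226 higher windows, out of 282 tested, between IV 11973697 and 12010896. All 41 tested windows of drh-2 and all 29 of prg-2 were higher, as were 34 of 38 in wago-2, 38 of 43 in rsd-3 and 19 of 20 in akap-17A. Near-equal neighbours lay beside 40 of the 226 in unc-22, 16 of the 41 in drh-2, 2 of the 29 in prg-2, 6 of the 34 in wago-2, 21 of the 38 in rsd-3 and 8 of the 19 in akap-17A. In tos-1 (V), 16 of 29 windows were higher, with a median log2 fold change of 2.42 against 0.44 in its other windows. The windows were split by the same test, so this gap is no measure of local enrichment. Its fullest higher window, 9339359 to 9339458, held 289 and 237 reads against 35 and 21 (2.63 ± 0.26). The fullest window of the gene, 9343659 to 9343758, held 801 and 791 reads against 429 and 389. With the fullest window alone, tos-1 was not called (0.43 ± 0.135, edgeR, adjusted p = 0.523).

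Some genes that did not pass as a whole held higher windows. rhgf-3 (I) had 113 of 309, but 107 of these had a near-equal neighbour and the fullest held 23 and 47 reads against 0 and 2. No stretch of enrichment is read from them. Y9D1A.1 (II) had 15 of 16 higher, with 175 and 157 reads against 20 and 15 in the fullest (2.64 ± 0.32), and 2 of the 15 lay beside a near-equal neighbour. noah-2 (IV) had 16 of 39, with 14 of the 16 beside one.

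At the retained intron of Y119C1B.10, the windows I 4555943 to 4556042 and 4556043 to 4556142 were higher in the tagged IP by 1.82 ± 0.42 and 2.65 ± 0.65 (edgeR, adjusted p = 0.026 and 0.0449). Neither exceeded the gene as a whole (2.39) by more than its SE, and both also hold exon sequence. At the cpt-2 intron, the window IV 11181745 to 11181844 was higher by 1.41 ± 0.31 (edgeR, adjusted p = 0.0197) and its neighbour was not (0.63 ± 0.37). The windows at the Y54G2A.36 intron (2.36 ± 0.73), at the uaf-1 intron (1.11 ± 0.36 and 1.55 ± 0.45) and at the ppw-1 splice site (0.38 ± 0.28 and 1.23 ± 0.37) did not pass.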
